A study of Mus musculus with 4 samples.

How the data were processed

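Single-nucleus RNA was measured with the 10x 3′ chemistry in 4 pooled libraries of hippocampus from B6 mice at 9 months, per the labels: WT, EKO, P301S and P301S/EKO, 1 library each. The deposited files hold whole-number UMI counts for 27998 genes per barcode and library. The submitters' processing notes name Cell Ranger with the mm10 genome, and Seurat for later steps. Versions of both tools and the handling of intron reads are not given in the sources used here. The tests run on the files found whole numbers of 0 or more, the same genes in each library and no barcode without counts. Gene positions came from GENCODE vM21, on GRCm38 (mm10).

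Groups were taken from the labels alone. Counts were analysed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, igraph 0.11.9 and scikit-learn 1.9.0, and drawn with matplotlib 3.10.9. Barcodes with at least 200 genes and at most 5% mitochondrial UMIs were kept. Scrublet, as in scanpy, scored doublets in each library with an expected rate of 0.06. Its own threshold called none, so the highest scores were removed at a rate of 0.8% per 1000 barcodes: 271 of 5505 barcodes in WT, 261 of 5460 in EKO, 74 of 2934 in P301S and 302 of 5576 in P301S/EKO. This left 5234, 5199, 2860 and 5274 nuclei.

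All kept nuclei were clustered together. Apoe, Prnp, Mapt, mitochondrial and sex-linked genes were left out of the clustering, as were genes seen in under 10 nuclei. Counts were scaled to 10000 per nucleus and log-transformed. The 2000 most variable genes were chosen with the library as batch key, scaled and reduced to 30 principal components. A graph of 15 neighbours was split by the Leiden method at resolution 1, with no correction for library. A cluster took the name of 1 of 18 fixed marker sets when at least 3 of the set's markers stood at least 1.5-fold above the other nuclei, the set had the highest mean and the cluster's top 10 genes held no more markers of another set. Names are written "microglia-like" and so on. Of the 18 clusters, 1 with 1069 nuclei had no name; it was counted with the neurons where shares among neurons are given.

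Counts were summed over the nuclei of a class in a library and given as CPM, scaled to a total of 1e6 in that class. Log2 ratios carry a prior of 0.5 UMI scaled to library size; folds of named genes are plain ratios of CPM. Members of a list needed at least 20 UMIs over the 2 libraries compared, other genes at least 50. The 4 comparisons made were: P301S over WT, P301S/EKO over P301S, EKO over WT and P301S/EKO over EKO. With 1 library per genotype no test between genotypes was made and no p-value is given; a model of the 2 factors without their interaction was not fitted. Intervals are 95% and hold counting error only: exact Poisson limits for levels, exact conditional binomial limits for ratios, Clopper-Pearson limits for shares (for a share of 0, the limit of 3 counts of the total), and 1000 Poisson redraws for list medians. For a count of 0, a fold is given as a lower bound against a floor of 3 counts. A percentile beside a list median is its place among 10000 random lists of genes matched for level in 20 bins.

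The lists were disease-associated microglia, homeostatic microglia, interferon response, antigen presentation, complement, lysosome, reactive astrocyte, homeostatic astrocyte, myelin, disease-associated oligodendrocyte, oligodendrocyte precursor and differentiation, cholesterol synthesis, lipid transport with liver X receptor targets, synaptic, immediate early, integrated stress and unfolded protein response, heat shock, nuclear genes of oxidative phosphorylation, ribosomal protein, sex-linked, and neuronal transcripts outside neurons. On the last list Snap25, Syt1, Nrgn, Camk2a and Slc17a7 are also synaptic members. Some homeostatic, complement, lysosome, myelin and oligodendrocyte precursor members are also markers that named the classes.

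Genes were named by a rule: Apoe, Prnp and Mapt in each library; per comparison and class the 3 highest and 3 lowest genes whose interval lay beyond 1.5-fold, in classes of at least 50 nuclei; up to 4 members of each list with the largest ratios; and up to 5 genes per direction and class that were at least 1.5-fold the same way in both comparisons of a factor without a shared library. A gene named in 1 comparison is also given in others where its level is set beside it, and a few further members of a list are given; those values, and Ttr, were chosen after the values were seen.

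The marker sets, lists, naming rule and the following alternatives were fixed before the data were examined: median-of-ratios scaling, at least 500 genes per nucleus, doublets kept, each library clustered alone, resolution 2, equal weight per nucleus, free RNA subtracted, and no minimum above 1 UMI. Added after the values were seen were: at least 1100 UMIs per nucleus; mixed nuclei left out, meaning nuclei outside neurons with a neuronal UMI share above 50% of the CA1 median; clustering without markers and list genes; naming markers left out of the lists; and all barcodes for the genotype check.

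The steps were tested on simulated data with known folds. Class totals were drawn from a Poisson distribution, the model that the intervals assume, so this checks the computation only. Spread between nuclei, mice or libraries was not simulated. Among microglia-like counts made like P301S over WT, the interval held the true value for 95.9% of 7072 genes set to no change, and for 91.0%, 92.5% and 100% of genes set 1.5-fold, 2-fold and 4-fold apart. Of genes set 2-fold apart, 100% had the right direction and 41.8% came out at least 2-fold apart; of genes set to no change, 0.255% did. For P301S/EKO over P301S the interval held the value of 95.8% of 6677 genes set to no change, and for P301S over WT in astrocyte-like counts of 96.0% of 2446. Random lists of 20 genes lay outside the 5th to 95th percentile in 12%, 10% and 4% of 50 draws in these 3 settings, where chance gives 10%.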

Results

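Nuclei from the hippocampi of B6 mice at 9 months were measured in 4 pooled libraries, 1 per genotype: WT (7 hippocampi), EKO (7), P301S (8) and P301S/EKO (7). EKO stands for loss of Apoe, and P301S for a human tau transgene with the P301S change. The study's title concerns tau-related neurodegeneration with and without apoE; its other 2 genotypes were not analysed here. In the order WT, EKO, P301S and P301S/EKO the files held 6145, 5982, 3156 and 6767 barcodes with 14251675, 10283013, 8369762 and 11358953 UMIs. Median UMIs per barcode were 1901, 1443.5, 2152.5 and 1394, median genes 977, 793, 1167.5 and 770.0. Barcodes with more than 5% mitochondrial UMIs made up 10.4%, 8.71%, 7.03% and 17.6%. After filtering, 5234, 5199, 2860 and 5274 nuclei were kept. Both libraries without Apoe were shallower per barcode than both libraries with it, so depth differed along with Apoe genotype. No genotype had a second library, so each difference given here is between 2 pools and has no replicate check.

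Apoe was nearly absent from the libraries labelled as knock-out. Apoe (chromosome 7, 19696109 to 19699188, minus strand, mm10) stood at 1899 CPM over all kept nuclei in WT, 16.2 in EKO, 6489 in P301S and 19.8 in P301S/EKO. It was 117-fold lower in EKO than in WT (log2 −6.88, interval −7.12 to −6.64), 327-fold lower in P301S/EKO than in P301S (log2 −8.35) and 3.42-fold higher in P301S than in WT (log2 1.77). Between the 2 knock-out libraries the log2 ratio was 0.29 (−0.03 to 0.62). Reads came from the 3′ end, so the counts show transcript ends and not whether a full transcript is made. Astrocyte-like nuclei held Apoe at 20336, 185, 29012 and 302 CPM in the order WT, EKO, P301S and P301S/EKO, and microglia-like nuclei at 2226, 9.31 (3 UMIs), 17991 and 14.4 CPM. A mouse Prnp cassette drives the tau transgene in a widely used P301S line, though the labels do not name the line. Prnp (chromosome 2, 131909928 to 131938429) was 1.65-fold higher in P301S than in WT and 1.68-fold higher in P301S/EKO than in EKO, at 375, 439.8, 619 and 738 CPM. Mapt, the mouse tau gene (chromosome 11, 104231390 to 104332090), was 1.59-fold and 1.32-fold higher in the same comparisons. Human MAPT is not in a mouse reference, so reads of the transgene may be counted as Mapt. Prnp and Mapt were read as checks of the labels, and their counts do not show that the mouse genes themselves rose.

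Microglia-like nuclei made up 4.57% of WT nuclei (4.02% to 5.17%), 2.69% of EKO (2.27% to 3.17%), 11.3% of P301S (10.2% to 12.5%) and 6.66% of P301S/EKO (6.00% to 7.36%). Among nuclei outside neurons their shares were 23.05%, 19.3%, 40.9% and 33.4%. Dentate granule neuron-like nuclei made up 12.9%, 26.1%, 5.66% and 19.1% of all nuclei and 16.1%, 30.3%, 7.83% and 23.9% of neurons. Inhibitory neuron-like nuclei stood at 11.2%, 11.5%, 20.5% and 11.1%, CA1 neuron-like at 15.1%, 11.4%, 9.23% and 11.8%, and CA2 or CA3 neuron-like at 9.86%, 8.77%, 6.85% and 8.76%. Subicular or cortical excitatory neuron-like nuclei held 26.4%, 21.6%, 26.0% and 22.5%. Oligodendrocyte-like nuclei stood at 5.46%, 3.42%, 4.23% and 5.29%, astrocyte-like at 5.33%, 3.79%, 4.41% and 3.83%, and oligodendrocyte precursor-like at 1.13%, 1.69%, 1.61% and 1.95%. Endothelial cell-like nuclei made up 2.50%, 1.31%, 2.97% and 1.19%. Choroid plexus epithelium-like nuclei numbered 10 in WT, 43 in P301S, 17 in P301S/EKO and 0 of 5199 in EKO, which allows up to 0.0577% (3 nuclei of the total). These shares lie beside the depth gap named above. Among nuclei outside neurons the lower microglia-like share without Apoe was not kept with at least 1100 UMIs per nucleus. There WT stood at 25.2% (22.5% to 28.2%) and EKO at 31.0% (26.3% to 36.1%). P301S stood at 42.5% (38.9% to 46.2%) and P301S/EKO at 44.6% (40.6% to 48.6%). These intervals overlap within each pair, as do those of WT and EKO without this minimum (20.5% to 25.7% and 16.5% to 22.4%). Among all nuclei the share without Apoe stayed lower, with 234 of 4814, 112 of 3805, 316 of 2759 and 272 of 3701. With at least 500 genes the shares outside neurons were 23.4%, 26.4%, 41.6% and 40.9%. With nuclei holding much neuronal RNA left out, EKO lay above WT and P301S/EKO below P301S: 8.78%, 13.3%, 24.5% and 23.1% of nuclei outside neurons and 0.974%, 1.44%, 4.53% and 3.13% of all nuclei in the same order.

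**Figure D1:**
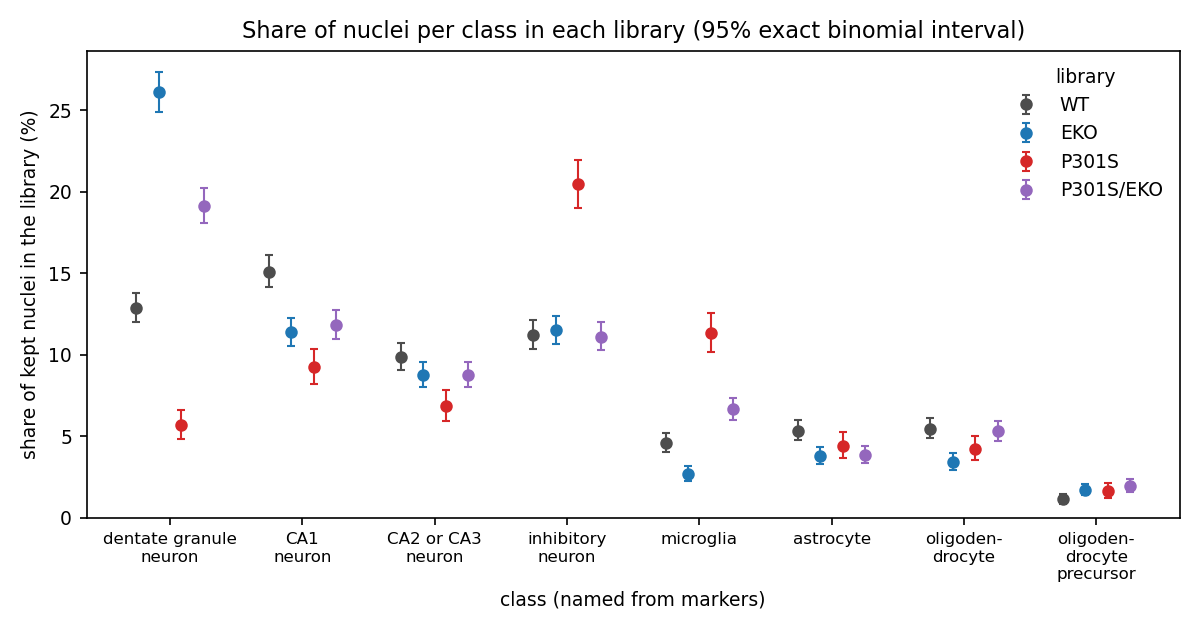
Share of kept nuclei in each library (y axis, percent) for 8 classes (x axis); points are shares and bars 95% exact binomial intervals. Dentate granule neuron-like nuclei were 26.1% of the EKO and 5.66% of the P301S library, and microglia-like nuclei 2.69% and 11.3%.

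P301S was set beside WT to see how the classes of the hippocampus differ with the tau transgene present. Spp1 and Cd74 headed the genes higher in P301S microglia-like nuclei. Spp1, which encodes the secreted protein osteopontin (chromosome 5, 104435118 to 104441050), stood at 328 CPM against 6.25 in WT, 52.5-fold higher (25.3 to 131). Cd74, the invariant chain of class II antigen presentation (chromosome 18, 60803848 to 60812652), was 27.3-fold higher (17.1 to 46.3), at 438 against 16.1 CPM. Itgax, which encodes the integrin CD11c, had 57.1 CPM in P301S and no count in WT, at least 21.3-fold higher. The glucose and fructose carrier gene Slc2a5 was 4.09-fold lower (2.61 to 6.62).

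Disease-associated microglia genes had a median log2 ratio of 1.87 (1.72 to 2.23; percentile 100), with 24 of 26 measured members at least 1.5-fold higher, 0 lower and 2 within. Cst7 and Ch25h, at 0 in WT, were at least 12.1-fold and 6.05-fold higher, Gpnmb was 9.04-fold higher and Trem2 2.56-fold. Antigen presentation genes stood at 2.83 (2.42 to 3.16), with 13 of 14 higher, among them H2-Aa (12.2-fold), H2-Ab1 (11.1-fold) and H2-D1 (8.32-fold). Interferon response genes had a median of 2.52 (1.94 to 3.11), 15 of 17 higher; Oasl2 was at least 15.0-fold and Ifit1 at least 7.10-fold higher, both without a WT count, and Ifi204 25.6-fold (6.82 to 216, on 2 WT counts). Complement genes stood at 1.10 with 8 of 9 higher, C4b 19.6-fold (13.4 to 30.0) and C1qa 3.04-fold, and lysosome genes at 0.84 with 18 of 28 higher, Ctsd 4.17-fold and Ctsz 3.29-fold. The homeostatic microglia genes were split: 5 of 19 were higher, 6 lower and 8 within, and their median of 0.22 and mean of −0.02 differ in sign. P2ry12 was 2.75-fold lower (2.00 to 3.82) and Tmem119 (chromosome 5, 113793729 to 113800516) 2.23-fold lower (1.69 to 2.95). Lipid transport and liver X receptor genes had a median of 0.42, with Abca1 3.73-fold and Apod 2.97-fold higher.

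In P301S astrocyte-like nuclei Serpina3n, a serine protease inhibitor gene (chromosome 12, 104406729 to 104414329), had 204 CPM against 3.93 on 2 WT counts, 51.9-fold higher (13.7 to 439). The intermediate filament genes Vim and Gfap were 10.7-fold (7.55 to 15.5) and 7.69-fold higher (6.70 to 8.86). Gfap (chromosome 11, 102887336 to 102900912) reached 3825 CPM. The reactive astrocyte list had a median of 2.73 (2.37 to 3.00), with 16 of 18 members higher and 0 lower, including Cd44 (25.9-fold, 6.56 to 224, on 2 WT counts) and Osmr (11.3-fold). Antigen presentation genes stood at 1.94 with 7 of 7 higher, B2m 5.98-fold and H2-D1 5.29-fold. Complement genes stood at 2.68 with 6 of 6 higher: C3 had no WT count and was at least 14.9-fold higher, and C4b (chromosome 17, 34728380 to 34743882) was 6.63-fold higher (5.15 to 8.63). C1qa, a microglial marker, was 4.27-fold higher in the same nuclei, beside the larger microglia-like share. Flrt3, which encodes an adhesion protein, was 8.76-fold lower (2.82 to 44.0, on 3 P301S counts), Nell2 3.45-fold and Ank3 2.97-fold; neuronal transcripts in these nuclei had a median of −0.70 (−0.97 to −0.53).

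Cholesterol synthesis genes were lower in the same astrocyte-like nuclei, with a median of −1.22 (−1.54 to −0.84; percentile 0.00) and 12 of 15 members lower, 0 higher and 3 within. Fdft1 was 3.63-fold lower. Sqle, the gene of squalene epoxidase (chromosome 15, 59315077 to 59331192), was 3.96-fold lower (2.15 to 7.96), at 42.2 against 167 CPM. The list was also lower in oligodendrocyte-like nuclei (−0.81, 10 of 15 members), inhibitory neuron-like (−0.54, 11 of 22), microglia-like (−0.54, 9 of 20), dentate granule neuron-like (−0.43, 5 of 15) and CA2 or CA3 neuron-like nuclei (−0.33, 9 of 22), and near 0 in CA1 neuron-like nuclei (−0.12). Lipid transport and liver X receptor genes ran the other way in astrocyte-like nuclei, at 0.69 (0.42 to 0.86) with 11 of 21 higher and 2 lower: Abca1, the cholesterol export gene, was 5.37-fold higher (3.34 to 8.91) and Srebf1 2.50-fold. Homeostatic astrocyte genes had a median of 0.31 with 8 of 23 higher and 3 lower, Kcnj10 4.21-fold and Aqp4 2.30-fold higher.

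**Figure D2:**
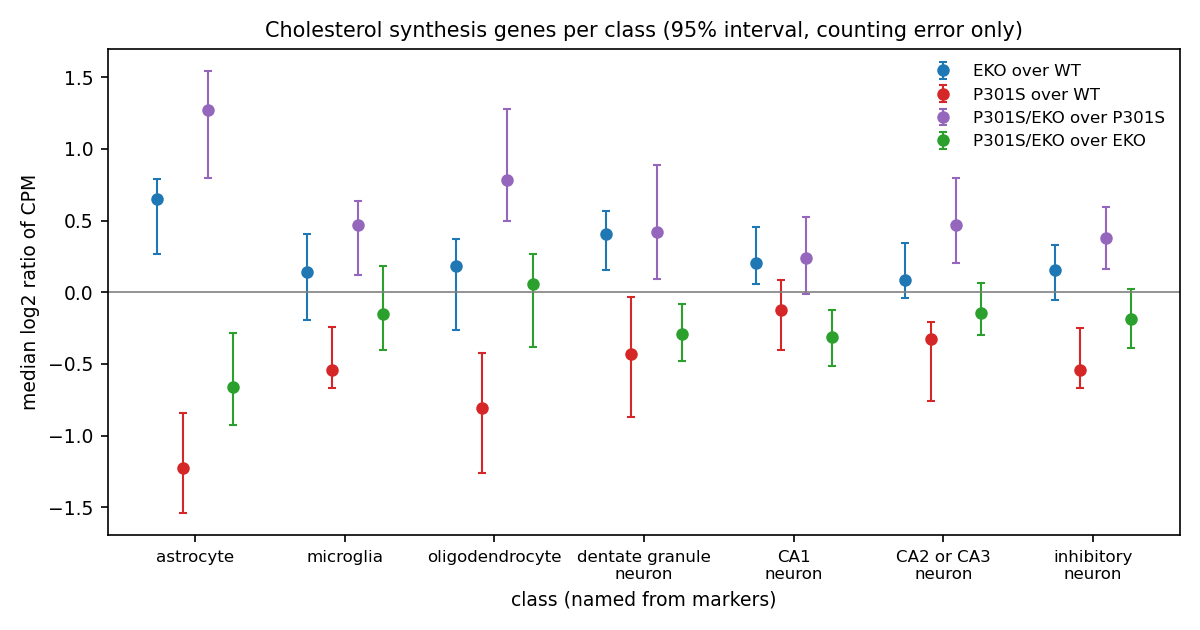
Median log2 ratio of CPM of the cholesterol synthesis genes (y axis) in 7 classes (x axis), 1 color per comparison; bars are 95% intervals of counting error. In astrocyte-like nuclei the medians were −1.22 for P301S over WT and 1.27 for P301S/EKO over P301S.

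In P301S oligodendrocyte-like nuclei C4b was 21.4-fold higher than in WT (13.7 to 35.1) and Cdkn1a, a cell cycle inhibitor gene, 34.8-fold (8.72 to 303, on 2 WT counts). Disease-associated oligodendrocyte genes had a median of 1.68 (1.18 to 1.96), with 11 of 14 higher and 1 lower; B2m was 6.03-fold and Serpina3n 5.06-fold higher. Complement genes stood at 2.68 and antigen presentation genes at 1.85, each with 4 of 4 members higher, and interferon response genes at 0.53. The microglial marker C1qa was 8.39-fold higher in the same nuclei (5.18 to 14.1), beside the larger microglia-like share. Myelin genes had a median of 0.60 with 11 of 19 higher, Tspan2 2.85-fold and Myrf 1.94-fold. The long noncoding RNA Neat1 was 2.70-fold higher (2.45 to 2.99). Dentate transcripts ran lower in these nuclei, as did the dentate share of the library: C1ql2 4.98-fold and Plk5 15.5-fold (4.15 to 130, on 2 P301S counts). In precursor-like nuclei the precursor and differentiation list stood at 0.57 with 7 of 14 higher, Gpr17 3.31-fold and Sox6 3.26-fold, from 46 P301S nuclei. Gpr17 and Sox6 also named the class, and 57.6% of these nuclei in WT and 41.3% in P301S held much neuronal RNA. Endothelial cell-like nuclei had interferon response genes at 0.82 with 11 of 15 higher, Gbp2 2.62-fold and Ifit3 3.09-fold.

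C1ql2, which marks dentate granule neurons, was 2.54-fold lower in dentate granule neuron-like nuclei (2.00 to 3.27) and Plk5 2.62-fold lower, while Znrf2 was 5.14-fold higher. The immediate early gene Nr4a2 had no count in P301S dentate granule neuron-like nuclei, at least 3.10-fold lower than 30.4 CPM in WT; the list's median was −0.54 (−0.81 to 0.00), with 5 of 12 members lower and 3 higher. In CA1 neuron-like nuclei the transcription factor gene Etv1 was 3.28-fold, the zinc carrier gene Slc30a3 2.69-fold and Il1rapl1 2.06-fold lower. Epha5 was 1.89-fold lower (1.73 to 2.08) in CA2 or CA3 neuron-like nuclei, and in inhibitory neuron-like nuclei Adamts15 was 3.42-fold higher and Ntng1 1.69-fold lower. Synaptic genes stayed near 0: medians of 0.06 in dentate granule, 0.03 in CA1, −0.07 in CA2 or CA3 (mean 0.03) and −0.02 in inhibitory neuron-like nuclei (mean 0.00). The integrated stress and unfolded protein response list lay between −0.12 and 0.11 in these classes, with a mean of 0.04 beside the −0.12 of inhibitory neuron-like nuclei. Heat shock genes stood at 0.35 in CA1 and −0.23 in dentate granule neuron-like nuclei. Ribosomal protein genes, read as a check of RNA quality, were 0.39 in microglia-like and 0.51 in astrocyte-like nuclei.

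As a description of 2 libraries, 340 microglia-like genes were at least 2-fold higher and 92 lower of 7272 with enough counts, and 173 higher and 139 lower of 2646 in astrocyte-like nuclei. The median of all genes sat at 0.12 in CA1 and 0.14 in CA2 or CA3 neuron-like nuclei, and ratios in those classes are to be read relative to it. With nuclei holding much neuronal RNA left out, 176 microglia-like and 201 astrocyte-like genes were 2-fold apart in place of 432 and 312 (494 astrocyte-like with each library clustered alone), the homeostatic microglia median was 0.06 and Insig1, 2.28-fold lower in microglia-like nuclei, turned higher. Leaving nuclei out also leaves fewer genes with at least 50 UMIs, which can by itself lower the counts of 2-fold genes. With free RNA subtracted, the homeostatic astrocyte median was −0.01 and the disease-associated oligodendrocyte median 0.92.

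**Figure D3:**
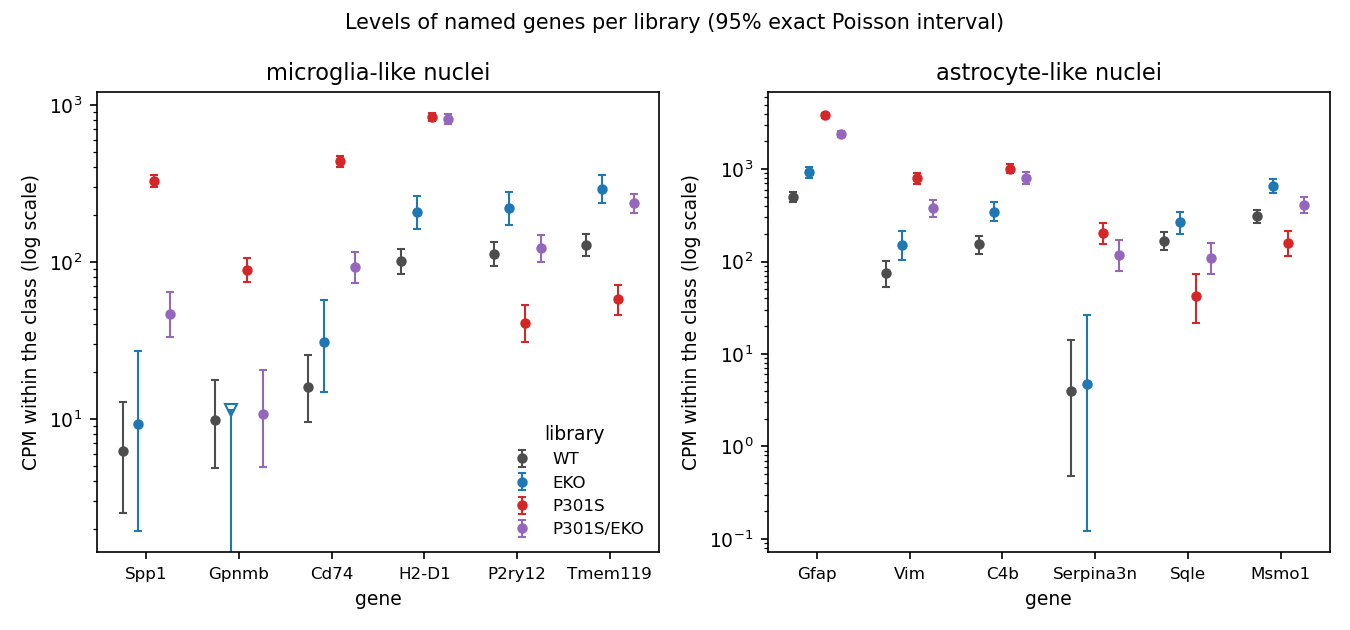
Level within the class (y axis, CPM on a log scale) of 6 genes each in microglia-like and astrocyte-like nuclei (x axis), 1 color per library; bars are 95% exact Poisson intervals, and the open triangle is the upper limit of a count of 0. Spp1 stood at 328 CPM in P301S and 46.8 in P301S/EKO, and Tmem119 at 57.8 and 236.

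P301S/EKO was set beside P301S to see how the same classes differ when Apoe is lost in the presence of the transgene. Microglia-like nuclei lay at lower levels of disease-associated genes. The homeostatic list had a median of 0.48 (0.27 to 0.63), with 8 of 20 members at least 1.5-fold higher and 2 lower; without the 7 members that also named the class its median was 0.05. Spp1 was 7.02-fold lower (5.06 to 9.99) and the glycoprotein gene Gpnmb 8.22-fold lower (4.19 to 18.4), at 10.8 against 88.8 CPM. Tmem119 and Selplg, which mark microglia at rest, were 4.09-fold (3.15 to 5.36) and 2.62-fold higher (2.23 to 3.10). P2ry12, the purine receptor gene, was 3.00-fold higher (2.15 to 4.21), at 122 CPM against 40.9 in P301S and 112 in WT.

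The disease-associated microglia list had a median of −0.80 (−1.02 to −0.50; percentile 0.00), with 14 of 26 members lower, 0 higher and 12 within. Igf1 had no count in P301S/EKO and was at least 5.87-fold lower, and Cybb was 14.4-fold lower (3.78 to 122, on 2 counts). Itgax was 4.76-fold lower, while Trem2 was 1.07-fold higher. Antigen presentation genes had a median of −0.58 (−0.88 to −0.27) with 7 of 15 lower: H2-Eb1 was 6.36-fold, H2-Aa 5.65-fold, Cd74 4.74-fold and H2-Ab1 4.13-fold lower, while H2-D1 was 1.03-fold and H2-K1 1.29-fold lower and B2m 1.11-fold higher. Interferon response genes stood at −0.21 (−0.51 to 0.02) with 4 of 19 lower, of which Ifi44 was 12.9-fold lower (2.09 to 533, on 1 count). Complement genes had a median of −0.02, with C4b 3.03-fold lower (2.51 to 3.69) and C1qa 1.09-fold. Lysosome genes had −0.06, with 25 of 28 members within 1.5-fold. Among lipid transport and liver X receptor genes (−0.12) Abca1 was 2.78-fold lower and Scd1 3.92-fold higher. The dentate transcript C1ql3 was 312 against 118 CPM in these nuclei, beside the larger dentate share.

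Astrocyte-like nuclei showed Junb 4.83-fold lower (2.66 to 9.50) and the Notch target gene Hes5 5.01-fold higher (2.70 to 9.98). The reactive astrocyte list stood at −0.55 (−0.76 to −0.32; percentile 0.01), with 9 of 20 lower and 1 higher. The cytokine receptor gene Osmr was 5.45-fold lower (2.29 to 15.8), Cxcl10 4.88-fold (1.41 to 26.0, on 3 counts), Serping1 3.96-fold and Cd44 3.56-fold. Vim was 2.12-fold, Serpina3n 1.72-fold and Gfap 1.59-fold lower (1.44 to 1.76), and Gfap had 2402 CPM against 497 in WT. Complement genes had a median of −1.31 with 4 of 6 lower, C3 5.38-fold (1.86 to 21.3) and C1qa 2.36-fold, again beside a smaller microglia-like share. Antigen presentation genes had a median of 0.15 and a mean of −0.47, with H2-Q4 19.8-fold lower (3.21 to 815, on 1 count). Interferon response genes stood at −0.29.

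Cholesterol synthesis genes were higher in P301S/EKO than in P301S astrocyte-like nuclei, with a median of 1.27 (0.79 to 1.54; percentile 100) and 9 of 12 members higher. Fdft1 was 4.65-fold (1.85 to 13.9), Idi1 3.49-fold and Msmo1 2.58-fold higher (1.80 to 3.76). Sqle was 2.61-fold higher, at 110.3 CPM against 42.2 in P301S and 167 in WT. The list stood at 0.78 in oligodendrocyte-like nuclei (7 of 12 higher), 0.47 in microglia-like (7 of 19) and in CA2 or CA3 neuron-like (8 of 18), 0.42 in dentate granule (7 of 16), 0.38 in inhibitory (6 of 20) and 0.24 in CA1 neuron-like nuclei. Lipid transport and liver X receptor genes in astrocyte-like nuclei had −0.26 with 6 of 18 lower, Pltp 2.75-fold and Apod 2.05-fold. Homeostatic astrocyte genes stood at 0.37.

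In oligodendrocyte-like nuclei C4b was 2.16-fold (1.71 to 2.73) and Cdkn1a 4.49-fold lower (2.04 to 10.9). Disease-associated oligodendrocyte genes had a median of −0.19 (−0.44 to 0.05) with 5 of 14 lower and 2 higher, complement genes −1.06, antigen presentation genes −0.15 and interferon response genes 0.38; C1qa was 2.33-fold lower in these nuclei, beside the smaller microglia-like share. Myelin genes stood at 0.02, with Ugt8a 2.24-fold and Cnp 1.86-fold higher. Precursor and differentiation genes had −0.43 in precursor-like nuclei, with Bcas1 2.44-fold and Myrf 2.43-fold lower. Interferon response genes were higher in endothelial cell-like nuclei, at 0.72 (0.32 to 1.10) with 9 of 14 higher: Ifit1 was 3.64-fold (1.95 to 6.96), Irf7 2.95-fold and Oasl2 2.71-fold higher, and H2-K1 2.10-fold.

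Dentate granule neuron-like nuclei had C1ql2 3.49-fold higher (2.76 to 4.47), at 856 CPM against 245 in P301S and 624 in WT. The enkephalin gene Penk was 8.04-fold higher (2.14 to 67.8, on 2 P301S counts) and Timp4, a metalloproteinase inhibitor gene, 3.43-fold. Immediate early genes stood at 0.52 (−0.04 to 0.78), Nptx2 2.81-fold higher. In CA1 neuron-like nuclei Slc30a3 was 3.33-fold, Egr4 2.83-fold (1.88 to 4.39), Timp4 2.73-fold and Arc 1.60-fold higher. CA2 or CA3 neuron-like nuclei had Sqle 2.60-fold (1.61 to 4.39) and Fdps 2.41-fold higher, and inhibitory neuron-like nuclei the cortistatin gene Cort 2.30-fold (1.61 to 3.30) and Asns 2.00-fold. Synaptic genes had medians of −0.05 in dentate granule, −0.10 in CA1, −0.10 in CA2 or CA3 and −0.05 in inhibitory neuron-like nuclei. Oxidative phosphorylation genes stood at 0.48 in oligodendrocyte-like nuclei (10 of 33 higher) and between 0.11 and 0.19 in the other classes measured.

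As a description of 2 libraries, 66 microglia-like genes were at least 2-fold higher and 273 lower of 6877, and 19 higher and 41 lower of 1595 astrocyte-like genes; the median of all genes was −0.10 in CA1 and −0.15 in CA2 or CA3 neuron-like nuclei. With nuclei holding much neuronal RNA left out, the disease-associated median was −0.38 and the homeostatic median 0.28 (−0.03 to 0.62), with 94 microglia-like genes 2-fold apart in place of 339; 96 astrocyte-like genes were 2-fold apart in place of 60 with doublets kept, and with at least 1100 UMIs per nucleus the reactive astrocyte median was −0.28.

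**Figure D4:**
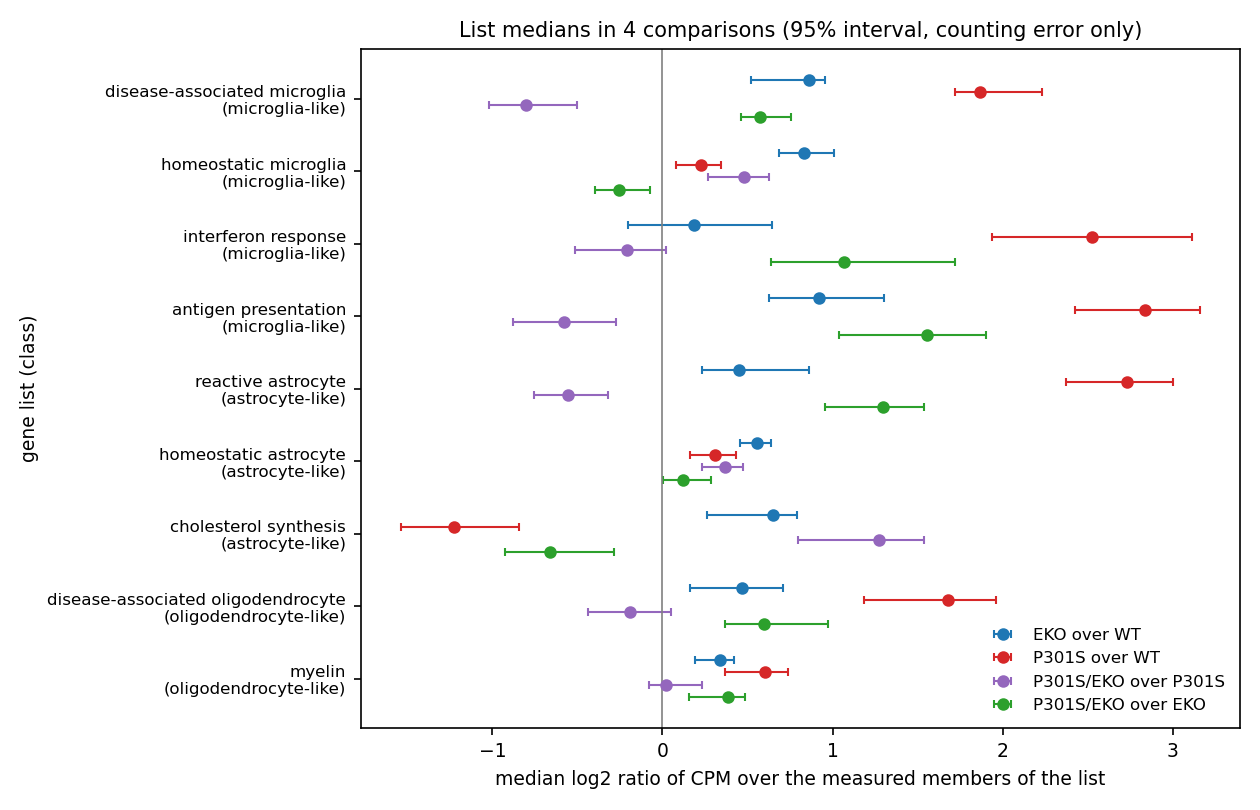
Median log2 ratio of CPM over the measured members of 9 gene lists (x axis) in the class named on the y axis, 1 color per comparison; bars are 95% intervals of counting error. Disease-associated microglia genes stood at 1.87 for P301S over WT, −0.80 for P301S/EKO over P301S and 0.86 for EKO over WT.

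EKO was set beside WT to see how the classes differ when Apoe is lost without the transgene. Lag3, an immune checkpoint receptor gene, was 6.16-fold higher (4.01 to 9.61) in EKO microglia-like nuclei, Cd14 4.28-fold and Ctss, which encodes cathepsin S, 2.89-fold (2.46 to 3.40). Rnf121, a ubiquitin ligase gene (chromosome 7, 102019137 to 102065469), was 30.8-fold lower (13.1 to 95.2), at 15.5 against 478 CPM. Disease-associated and homeostatic genes both had medians above 0, which were smaller among nuclei of 1500 to 3500 UMIs, at 0.39 (0.14 to 0.68) and 0.24 (0.13 to 0.51).

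Disease-associated microglia genes had a median of 0.86 (0.52 to 0.96), with 9 of 15 higher and 1 lower. Cd68 was 2.38-fold and Trem2 2.27-fold higher (1.77 to 2.88), while Lpl was 7.76-fold lower (1.28 to 318, on 1 EKO count). Homeostatic microglia genes stood at 0.83 (0.68 to 1.01), 12 of 19 higher and 0 lower, among them Siglech 2.79-fold, Selplg 2.48-fold, Csf1r 2.45-fold and Tmem119 2.27-fold. Complement genes had a median of 1.13 (0.88 to 1.30) with 8 of 8 higher, C1qb 2.43-fold and C1qa 2.16-fold. Lysosome genes stood at 0.62 with 16 of 27 higher, Laptm5 2.48-fold, and antigen presentation genes at 0.92 (0.63 to 1.30) with 7 of 7 higher, Tapbp 2.61-fold and H2-D1 2.06-fold (1.501 to 2.81). Interferon response genes had a median of 0.19 on 5 members, and Spp1 had 6.25 CPM in WT and 9.31 CPM on 3 counts in EKO. Lipid transport and liver X receptor genes had a median of 0.14 and a mean of −0.14. Nuclear genes of oxidative phosphorylation were lower, at −0.42 (−0.62 to −0.29) with 12 of 34 members, as were heat shock genes, at −0.44, and ribosomal protein genes, at −0.27 (−0.39 to −0.10).

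Astrocyte-like nuclei of EKO had Myoc 4.32-fold (3.08 to 6.10), Etnppl, a phospholipid pathway gene, 2.94-fold and the RNA-binding gene Msi2 2.28-fold higher. Cholesterol synthesis genes stood at 0.65 (0.26 to 0.79) with 10 of 18 higher and 1 lower: Idi1 was 3.27-fold (1.67 to 6.52), Msmo1 2.12-fold and Sqle 1.59-fold higher. Among nuclei of 1000 to 2500 UMIs the median was 0.25 (−0.17 to 0.61), an interval that includes 0. In other classes the list stood at 0.41 in dentate granule, 0.20 in CA1, 0.15 in inhibitory and 0.09 in CA2 or CA3 neuron-like nuclei, 0.18 in oligodendrocyte-like, 0.14 in microglia-like and −0.24 in precursor-like nuclei. Reactive astrocyte genes had a median of 0.45 (0.23 to 0.86), with 4 of 9 higher, Thbs4 2.72-fold, C4b 2.26-fold, Vim 2.04-fold and Gfap 1.85-fold (1.53 to 2.24). Homeostatic astrocyte genes stood at 0.55 with 9 of 23 higher, Slc4a4 1.69-fold. Antigen presentation genes had a median of 0.45, lysosome genes 0.15 and interferon response genes −0.02. Neuronal transcripts in these nuclei stood at −0.61 (−1.002 to −0.41).

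Oligodendrocyte-like nuclei had Neat1 2.07-fold (1.86 to 2.30) and Igsf3 2.98-fold higher. Disease-associated oligodendrocyte genes had a median of 0.47 with 3 of 10 higher and 1 lower, Klk6 3.04-fold higher (1.14 to 8.30), and myelin genes 0.34. Precursor and differentiation genes stood at 0.83 (0.23 to 1.10) with 7 of 13 higher in precursor-like nuclei; Gpr17 was 3.57-fold (1.74 to 7.86), Sox6 3.16-fold and Ptprz1 2.41-fold higher. Of these nuclei 57.6% in WT and 13.6% in EKO held much neuronal RNA, with median UMIs of 1826 and 722, and without the members that also named the class the median of oligodendrocyte precursor and differentiation genes was 0.02. In dentate granule neuron-like nuclei Sox11, a gene of immature neurons, was 2.26-fold higher, and in inhibitory neuron-like nuclei Cort 4.17-fold (2.88 to 6.16), Slc7a3 4.01-fold and Crhbp 1.81-fold. The integrated stress and unfolded protein response list stood at 0.27 in dentate granule, 0.31 in CA1, 0.32 in CA2 or CA3 and 0.37 in inhibitory neuron-like nuclei; in CA1 neuron-like nuclei 6 of 14 members were higher, Ddit3 3.53-fold (1.35 to 10.2) and Hspa5 1.53-fold. Synaptic genes lay at 0.02 (mean −0.02), 0.06, −0.02 and −0.15 in the same order of classes. The pituitary hormone genes Gh (chromosome 11, 106300271 to 106301865) and Prl (chromosome 13, 27057570 to 27065205) had 1128 and 224 CPM in EKO CA1 neuron-like nuclei and no count in WT, but 1 of the 591 nuclei held 1198 of the 1231 Gh UMIs, and the richest nucleus for Prl 225 of 244.

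As a description of 2 libraries, 85 microglia-like genes were at least 2-fold higher and 178 lower of 4765, and 47 higher and 108 lower of 2276 astrocyte-like genes. Median UMIs of microglia-like nuclei were 4004 in WT and 1887 in EKO, and 80.8% and 48.6% of them held much neuronal RNA. With those nuclei left out, 34 microglia-like and 38 astrocyte-like genes were 2-fold apart in place of 263 and 155 (439 and 52 with free RNA subtracted, 452 microglia-like with equal weight per nucleus and 233 astrocyte-like with each library clustered alone), the disease-associated median was 0.52, the homeostatic median 0.53 and the reactive astrocyte median 0.12, and Trem2 was no longer higher (log2 −0.05); Klk6 was no longer higher with at least 500 genes per nucleus (log2 −0.16).

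P301S/EKO was set beside EKO to see how the classes differ with the transgene when Apoe is lost in both. H2-D1, a class I antigen presentation gene, was 3.90-fold higher (3.03 to 5.09) in P301S/EKO microglia-like nuclei and Lgals3bp 5.73-fold (2.53 to 16.0). Slc2a5 was 3.55-fold lower (2.10 to 6.05). Rnf121 was 29.1-fold higher (12.4 to 90.3). Antigen presentation genes had a median of 1.55 (1.04 to 1.90), with 7 of 10 higher and 0 lower: H2-K1 was 3.44-fold, B2m 2.96-fold and Tap1 7.73-fold higher (1.24 to 320, on 1 EKO count). Interferon response genes stood at 1.07 (0.64 to 1.72), 7 of 10 higher, with Ifi204 at least 3.22-fold and Oasl2 at least 2.83-fold higher, both without an EKO count. Disease-associated microglia genes had a median of 0.57 (0.46 to 0.76) with 8 of 17 higher; Spp1 was 5.02-fold (1.60 to 25.4, on 3 EKO counts) and Trem2 1.21-fold higher. Homeostatic microglia genes stood at −0.25 (−0.40 to −0.07), 4 of 19 lower, with P2ry12 1.80-fold, Siglech 1.62-fold and Csf1r 1.59-fold lower. Complement genes had 0.31, with C4b 3.87-fold higher (2.18 to 7.45), and lysosome genes 0.13, with Ctsd 1.51-fold higher.

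In astrocyte-like nuclei the reactive list stood at 1.29 (0.96 to 1.54; percentile 100), with 11 of 13 higher and 0 lower. Serpina3n was 24.9-fold (4.14 to 1019, on 1 EKO count), H2-T23 10.3-fold (2.56 to 90.1, on 2), Gfap 2.61-fold (2.21 to 3.08) and Vim 2.47-fold higher. Antigen presentation genes had a median of 1.86 with 6 of 6 higher, and complement genes 1.32 on 3 members, with C4b 2.31-fold and the microglial marker C1qa 2.58-fold higher (1.18 to 6.24), beside the larger microglia-like share. Cholesterol synthesis genes were lower, at −0.66 (−0.92 to −0.29; percentile 0.03) with 8 of 15: Sqle 2.41-fold (1.498 to 3.97), Fdps 2.40-fold and Srebf2 2.07-fold. In dentate granule, CA1, inhibitory and CA2 or CA3 neuron-like nuclei the list stood at −0.29, −0.31, −0.19 and −0.14, in microglia-like nuclei at −0.15 and in precursor-like nuclei at −0.21; in oligodendrocyte-like nuclei the median of 0.05 and mean of −0.06 differ in sign. Lipid transport and liver X receptor genes had 0.33, with Srebf1 2.37-fold and Abca1 2.12-fold higher. The myelin transcripts Mbp and Mobp were 3.10-fold and 3.65-fold higher in these nuclei, and Mbp 4.90-fold (4.26 to 5.64) in dentate granule neuron-like nuclei. Mbp in the latter stood at 383, 153, 533 and 749.6 CPM in WT, EKO, P301S and P301S/EKO. The oligodendrocyte-like shares of 5.46%, 3.42%, 4.23% and 5.29% did not follow that order. Within oligodendrocyte-like nuclei Mbp stood at 1030, 1307, 1792 and 1821 CPM in the same libraries. Since share and level both differed, the shares alone cannot show whether oligodendrocyte RNA makes this order.

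Oligodendrocyte-like nuclei had C4b 5.18-fold (3.11 to 9.16), H2-D1 6.18-fold (3.39 to 12.3) and H2-K1 5.02-fold higher. Disease-associated oligodendrocyte genes stood at 0.60 with 6 of 12 higher, complement genes at 1.64, antigen presentation genes at 1.79 and myelin genes at 0.38, with Opalin 2.04-fold higher; C1qa was 2.56-fold higher in these nuclei, beside a microglia-like share of 6.66% against 2.69%. Endothelial cell-like nuclei had interferon response genes at 1.30 (0.85 to 2.11) with 7 of 8 higher, Ifit1 10.1-fold (3.14 to 52.0, on 3 EKO counts) and Isg15 4.42-fold. Znrf2 was 10.5-fold higher in dentate granule neuron-like nuclei. Synaptic genes stood at −0.01, −0.10, −0.06 and 0.10 in dentate granule, CA1, CA2 or CA3 and inhibitory neuron-like nuclei. Ribosomal protein genes were 0.38 in microglia-like, 0.48 in astrocyte-like and 0.43 in dentate granule neuron-like nuclei, and oxidative phosphorylation genes 0.42, 0.46 and 0.46.

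As a description of 2 libraries, 89 microglia-like genes were at least 2-fold higher and 25 lower of 3905, and 56 higher and 24 lower of 1280 astrocyte-like genes. With nuclei holding much neuronal RNA left out 46 microglia-like genes were 2-fold apart in place of 114 (194 with equal weight per nucleus) and the disease-associated microglia median was 0.92, with equal weight per nucleus the homeostatic microglia median was −0.06, and the astrocyte-like cholesterol median was −0.28 with doublets kept and −0.45 (−0.95 to 0.02) over its 15 members among nuclei of 1000 to 2500 UMIs.

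Each factor was measured in 2 comparisons without a shared library, and their ratios were set side by side. For the transgene the correlation across genes was 0.53 (Spearman 0.55) in astrocyte-like and 0.20 (0.10) in microglia-like nuclei; genes are not independent replicates. Of 1275 astrocyte-like genes, 93 were at least 1.5-fold higher in both comparisons, where chance gives 40.7, and 56 lower in both, where chance gives 21.8. They included Gfap (log2 2.94 and 1.38), S100a6 (2.71 and 1.97), Lgals3bp (2.59 and 1.92) and Dbi (1.28 and 1.42), and on the lower side Sqle (−1.95 and −1.25). Of 3903 microglia-like genes 49 were higher in both (29.5 by chance), with H2-D1 (3.05 and 1.96), H2-K1 (3.07 and 1.77), C4b (4.27 and 1.93) and B2m (2.37 and 1.56), and 33 lower in both (16.9 by chance), with Slc2a5 (−2.01 and −1.80) and P2ry12 (−1.45 and −0.84); these 82 numbered 135 with equal weight per nucleus. In precursor-like nuclei the correlation was −0.02, with 2 genes higher in both (2.23 by chance) and 9 opposite (5.51 by chance). CA2 or CA3 neuron-like nuclei had 63 higher in both (32.6 by chance) but 4 lower in both (6.48 by chance) and 45 opposite (32.5 by chance). For loss of Apoe the correlation was 0.19 in microglia-like and 0.20 in astrocyte-like nuclei. In microglia-like nuclei 46 of 4748 genes were higher in both (19.98 by chance) and 103 lower (55.4 by chance), with Tmem119 (1.18 and 2.02), Selplg (1.31 and 1.39), Cst3 (0.82 and 0.86) and Lgmn (0.99 and 0.81) on the higher side; these 149 genes numbered 22 with nuclei holding much neuronal RNA left out and 236 with equal weight per nucleus. Astrocyte-like nuclei had 35 of 1471 higher in both (17.7 by chance), with Hes5 (1.22 and 2.28), Msmo1 (1.08 and 1.36) and Myoc (2.10 and 1.06), and 26 lower; these 61 numbered 32 without such nuclei and 28 with free RNA subtracted. Leaving out nuclei with much neuronal RNA also leaves fewer genes with enough counts, which can by itself lower these numbers of genes. Timp4 was higher in both in dentate granule (0.97 and 1.77), CA1 (1.02 and 1.44) and CA2 or CA3 neuron-like nuclei (0.78 and 0.98). Cort was higher in both in inhibitory neuron-like nuclei (2.04 and 1.19).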

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

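The test of dilution by neuronal RNA in microglia-like nuclei, the test over all 12 cholesterol members in the UMI window and the tests of DNA around Apoe were chosen after the data were seen; the other tests of UMIs per nucleus and the tests of the cholesterol genes over all nuclei were chosen before. Of the 9 tests, 8 came out against the explanation tested and 1 was undecided. Among them the dilution test restated the medians of its own pattern and could not have come out otherwise, so it is no evidence. The test on other chromosomes shows only that nearby DNA does not cover the genes there. Each was made on the same libraries that showed the pattern.

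Disease-associated microglia genes were lower and homeostatic microglia genes higher in P301S/EKO than in P301S, with a gap of 1.28 (0.87 to 1.501) between their medians. Dilution by neuronal RNA would move both lists alike, but the gap over all microglia-like nuclei restates the pattern and cannot test this. Transcripts of list members that neuronal RNA brings along may add to the gap. With mixed nuclei left out the gap was 0.66 (0.22 to 1.01), smaller but of the same sign. A difference in UMIs per nucleus might also make it, but in a window of 1500 to 3500 UMIs the gap was 0.81 (0.35 to 1.13), which argues against it as the sole source. The homeostatic side stays open, since its median of 0.48 (0.27 to 0.63) became 0.28 (−0.03 to 0.62) without mixed nuclei and 0.26 (−0.04 to 0.51) in the window, smaller and with intervals that include 0. It may also depend on the markers that named the class, since without them its median was 0.050, and whether loss of Apoe makes the gap stays open with 1 library per genotype.

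Cholesterol synthesis genes in astrocyte-like nuclei were lower in P301S than in WT and higher in P301S/EKO than in P301S. Free RNA shared by all nuclei could carry the same change, but over all kept nuclei the medians were −0.50 and 0.43. These lay outside the astrocyte-like limits of −1.57 to −0.86 and 0.77 to 1.52 from a further set of redraws. The all-nuclei medians rest on 25 members and the astrocyte-like ones on 15 and 12. Differences between libraries in the amount of free RNA were not covered by this test. UMIs per nucleus could likewise shift the list, but in a window of 1000 to 2500 UMIs the P301S over WT median was −1.48 (−1.89 to −0.92), which argues against it. For P301S/EKO over P301S the window gave 1.34 (0.72 to 2.02) on the 4 members with enough counts and 1.18 (0.69 to 1.72) on all 12, which also argues against it. The share of the change due to Apoe, to the transgene or to the pools stays open.

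A total of 11 genes were at least 1.5-fold apart in the same direction in both EKO comparisons in at least 4 classes: Timp4 and Zfp507 higher, and AY036118, Rnf121, Ttr, Fam160b2, H3f3a, Cntnap2, Kansl1l, Qpctl and Zmat3 lower. Other DNA carried along with the Apoe change on chromosome 7 might do this for genes nearby. Of the 11, 8 lay on other chromosomes, which this explanation does not cover, so it leaves those 8 without an account. For the 3 on chromosome 7 (0.880 expected among 4224 genes tested) it stays open. Qpctl at 19139702 lay within 10 Mb of Apoe (0.161 expected, limit 1), and Zfp507 at 35772343 and Rnf121 at 102019137 lay further away. Ttr stood at 479, 9.73, 1787 and 593.5 CPM in WT, EKO, P301S and P301S/EKO. Rnf121 stood at 386, 22.3, 746 and 373 CPM. In P301S/EKO Rnf121 lay near and Ttr above the WT level, both far above EKO. The libraries without Apoe thus did not share a low level of these genes. Ttr, a choroid plexus gene, was also seen in other classes, at 300, 12.4, 1372 and 438 CPM in microglia-like nuclei in that order. In CA1 neuron-like nuclei it stood at 245, 10.1, 812 and 222 CPM. Choroid plexus epithelium-like nuclei numbered 10 of 5234, 0 of 5199, 43 of 2860 and 17 of 5274. These shares ranked the libraries as Ttr did over all kept nuclei. In CA1 neuron-like nuclei WT lay above P301S/EKO, but their intervals overlapped (222 to 269 and 195 to 250 CPM). Free RNA from choroid plexus might account for Ttr, which was not tested. Apart from Apoe genotype, lower depth in both EKO libraries and the makeup of the pools were not tested for the 11 genes.

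Further pairs of list medians differed in sign between the comparisons of a factor, and none of these differences was tested. Members needed at least 20 UMIs, so the members of a list can differ between the comparisons of a pair. Disease-associated microglia genes stood at 0.86 for EKO over WT on 15 members and −0.80 for P301S/EKO over P301S on 26. With mixed nuclei left out these medians were 0.52 and −0.38. Homeostatic microglia genes stood at 0.83 for EKO over WT, a gap of −0.03 (−0.17 to 0.38) to the disease-associated median. The rise of 0.86 was therefore not particular to disease-associated genes. The antigen presentation list in microglia-like nuclei and the reactive astrocyte list also had fewer measured members in EKO over WT than in P301S/EKO over P301S. Antigen presentation genes in microglia-like nuclei stood at 0.92 and −0.58 in the same pair, and reactive astrocyte genes at 0.45 and −0.55, where the 0.45 was 0.014 with free RNA subtracted, 0.12 with mixed nuclei left out, 0.15 with equal weight per nucleus and 0.21 with no minimum above 1 UMI. Oxidative phosphorylation genes had −0.42 and 0.19 in microglia-like, −0.21 and 0.13 in astrocyte-like and −0.27 and 0.48 in oligodendrocyte-like nuclei. For the same list dentate granule neuron-like nuclei had −0.52 and 0.13, CA1 neuron-like −0.19 and 0.12, and inhibitory neuron-like −0.12 and 0.18. Between P301S over WT and P301S/EKO over EKO, homeostatic microglia genes stood at 0.22 and −0.25; the 0.22 was −0.15 (−0.32 to 0.08) in the window of 1500 to 3500 UMIs and 0.059 with mixed nuclei left out, and the −0.25 was −0.063 with equal weight per nucleus. Oxidative phosphorylation genes in that pair had −0.18 and 0.42 in microglia-like, −0.28 and 0.46 in oligodendrocyte-like, −0.15 and 0.46 in dentate granule neuron-like and −0.14 and 0.45 in CA2 or CA3 neuron-like nuclei. Signs of RNA quality moved too: the median mitochondrial share per barcode was 0.939%, 0.587%, 0.948% and 1.48% in WT, EKO, P301S and P301S/EKO, and ribosomal protein genes stood at −0.27 for EKO over WT and 0.38 for P301S/EKO over EKO in microglia-like, −0.18 and 0.38 in oligodendrocyte-like and −0.43 and 0.43 in dentate granule neuron-like nuclei.

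Pituitary hormone genes stood out in the EKO library: Gh at 398, Prl at 168 and Cga at 31.2 CPM, each with 0 counts in WT. The 10 richest nuclei held 91.7% of the Gh, 90.0% of the Prl and 84.4% of the Cga UMIs, and 286, 158 and 53 of 5199 nuclei had at least 1. In CA1 neuron-like nuclei 1 nucleus held 97.3% of the Gh UMIs.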

How the results depend on the processing

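Planned before the data were seen were median-of-ratios scaling, at least 500 genes, doublets kept, each library clustered alone, resolution 2, equal weight per nucleus, free RNA subtracted and no minimum above 1 UMI; the settings at least 1100 UMIs, mixed nuclei left out, clustering without markers and list genes, naming markers left out and all barcodes were added after. No paired analysis was possible because each genotype was 1 pool of several mice. Intervals cover counting error and no difference between mice, dissections or runs, and the cause of each shift given here was not tested except where said. Clustered alone, the P301S library gave no oligodendrocyte-like and no precursor-like cluster, so those classes have no value there. The estimate of free RNA was cut at 50% for microglia-like nuclei in all 4 libraries, endothelial cell-like nuclei in WT and EKO and astrocyte-like nuclei in WT (24.7% in EKO, 36.6% in P301S and 28.1% in P301S/EKO), so its subtraction is cut short there. Over the list medians 2899 values under other settings lay within the interval, 202 moved out of it and 3, with an interval clear of 0 before, changed sign; for named genes these were 2817, 139 and 4. Median-of-ratios scaling moved none of the values listed in this section. Among the list medians not listed it moved 13 out of their interval and left 234 within it. It also moved 1 named gene and 1 count of genes the same way in both comparisons.

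With free RNA subtracted the median of disease-associated microglia genes was 1.00 in place of 0.86 for EKO over WT and −0.47 in place of −0.80 for P301S/EKO over P301S, where homeostatic microglia genes stood at 0.63. The reactive astrocyte median for EKO over WT was 0.014; the P301S over WT medians were −0.012 for homeostatic astrocyte (0.31 before, a change of sign), −1.78 for astrocyte-like cholesterol synthesis and 0.92 for disease-associated oligodendrocyte genes. Genes at least 2-fold apart in EKO over WT numbered 439 in place of 263 in microglia-like and 52 in place of 155 in astrocyte-like nuclei, and genes the same way in both EKO comparisons 28 in place of 61 in astrocyte-like nuclei.

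With mixed nuclei left out, disease-associated microglia medians were 0.52 for EKO over WT, −0.38 for P301S/EKO over P301S and 0.92 for P301S/EKO over EKO. Homeostatic microglia medians were 0.53 for EKO over WT and 0.059 for P301S over WT, and the reactive astrocyte median 0.12 for EKO over WT. By construction the microglia-like share became smaller, at 0.974%, 1.44%, 4.53% and 3.13% in WT, EKO, P301S and P301S/EKO, and the dentate granule share larger, at 14.3% in WT and 20.7% in P301S/EKO. Genes at least 2-fold apart numbered 34 (EKO over WT), 176 (P301S over WT), 94 (P301S/EKO over P301S) and 46 (P301S/EKO over EKO) in microglia-like nuclei, and 38 (EKO over WT) and 201 (P301S over WT) in astrocyte-like nuclei. Genes the same way in both EKO comparisons numbered 22 in microglia-like and 32 in astrocyte-like nuclei. Fewer nuclei also leave fewer genes with enough counts, which can by itself lower the numbers of genes given here. Insig1 changed sign to 1.51 for P301S over WT and Trem2 to −0.053 for EKO over WT, both in microglia-like nuclei.

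Clustered without markers and list genes, disease-associated microglia genes stood at 0.96 for EKO over WT and homeostatic ones at 0.36 for P301S over WT, with 89 astrocyte-like genes 2-fold apart in EKO over WT. Without the naming markers the homeostatic microglia medians were 0.53 for EKO over WT and 0.050 for P301S/EKO over P301S. With doublets kept the homeostatic microglia median was 0.61 for EKO over WT, the reactive astrocyte median 3.05 for P301S over WT and the astrocyte-like cholesterol median −0.28 for P301S/EKO over EKO; the WT microglia-like share was 3.94%, and 94 and 96 astrocyte-like genes were 2-fold apart in EKO over WT and P301S/EKO over P301S.

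With equal weight per nucleus homeostatic microglia medians were 0.63 for P301S/EKO over P301S and −0.063 for P301S/EKO over EKO, and the reactive astrocyte median 0.15 for EKO over WT. Microglia-like genes 2-fold apart numbered 452 for EKO over WT and 194 for P301S/EKO over EKO, and genes the same way 236 for EKO (149 before) and 135 for P301S (82 before).

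With at least 1100 UMIs the astrocyte-like lysosome median changed sign for EKO over WT (−0.033 against 0.15), the reactive astrocyte median was −0.28 for P301S/EKO over P301S and dentate granule shares were 11.9% in WT, 21.6% in EKO and 14.4% in P301S/EKO. Klk6 in oligodendrocyte-like nuclei changed sign for EKO over WT, from 1.53 to −0.069, and to −0.16 with at least 500 genes, where the dentate granule share of P301S/EKO was 18.0%. At resolution 2 the stress response median of CA1 neuron-like nuclei changed sign for P301S/EKO over EKO (0.059 against −0.23). With each library clustered alone 233 astrocyte-like genes were 2-fold apart in EKO over WT and 494 in P301S over WT.

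With no minimum above 1 UMI genes of few counts enter by construction. In the order EKO over WT, P301S over WT, P301S/EKO over P301S and P301S/EKO over EKO, 5657, 4638, 4729 and 4857 microglia-like and 5347, 5591, 5108 and 4885 astrocyte-like genes were then 2-fold apart, and the reactive astrocyte median for EKO over WT was 0.21. Genes the same way numbered 2436 in microglia-like and 2264 in astrocyte-like nuclei for EKO, and 2014 and 2249 for P301S.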

Other observations

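The measures in this part were chosen after the data were seen, apart from the sex-linked, ribosomal protein and neuronal transcript lists, which were fixed before.

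Y-linked genes were lower in both libraries without Apoe: Eif2s3y stood at 552, 293, 512 and 265 CPM in WT, EKO, P301S and P301S/EKO, Ddx3y at 178, 106, 224 and 101, Uty at 173, 87.9, 184 and 81.2 and Kdm5d at 104, 64.2, 110.0 and 51.1. Xist, the transcript of the silenced X chromosome, stood at 6.58, 9.84, 5.74 and 7.89 CPM. At least 1 Xist UMI was seen in 74 of 5234, 66 of 5199, 35 of 2860 and 66 of 5274 nuclei in the same order. Such nuclei were few in each library, which argues against many female mice in the pools without Apoe. No library known to be female shows how well Xist is detected here, and the labels give no sex per mouse.

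Microglia-like nuclei held much neuronal RNA: 80.8% of them in WT, 48.6% in EKO, 64.5% in P301S and 56.4% in P301S/EKO passed the limit for mixed nuclei. In oligodendrocyte-like nuclei these shares were 64.0%, 52.2%, 59.5% and 54.8%, in astrocyte-like nuclei 20.4%, 1.52%, 9.52% and 2.97%, and in precursor-like nuclei 57.6%, 13.6%, 41.3% and 20.4%. Neuronal transcripts in microglia-like nuclei had medians of 0.00 for EKO over WT, −0.28 for P301S over WT, 0.05 for P301S/EKO over P301S and −0.27 for P301S/EKO over EKO. In oligodendrocyte-like nuclei they stood at 0.06, −0.21, 0.01 and −0.21, and in endothelial cell-like nuclei at 0.10, −0.52, −0.03 and −0.36.

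Dentate transcripts were seen outside dentate granule neurons: C1ql2 stood at 206, 329, 37.3 and 242 CPM in microglia-like nuclei and at 219.7, 481, 44.2 and 293 CPM in oligodendrocyte-like nuclei, in the order WT, EKO, P301S and P301S/EKO, at 145, 85.5, 17.6 and 61.3 CPM in astrocyte-like nuclei and at 35.1, 56.8, 4.13 and 20.5 CPM in CA1 neuron-like nuclei. C1ql3 stood at 455, 499.8, 118 and 312 CPM in microglia-like and at 498, 559.9, 110.4 and 376 CPM in oligodendrocyte-like nuclei. Levels were lowest in P301S, the library with the smallest dentate share. C1ql2 in astrocyte-like and CA1 neuron-like nuclei was higher in WT than in P301S/EKO, against the order of the shares. So was C1ql3 in microglia-like and oligodendrocyte-like nuclei. For C1ql2 in CA1 neuron-like nuclei the intervals of WT and P301S/EKO overlapped (26.9 to 44.8 and 13.2 to 30.5 CPM). Ttr, a choroid plexus gene, was found in 2170 of 5234 WT nuclei and 71 of 5199 EKO nuclei, with 10 and 0 choroid plexus epithelium-like nuclei.

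Ribosomal protein genes were lower in EKO than in WT and higher in P301S/EKO than in EKO in neurons and microglia-like nuclei: −0.43 and 0.43 in dentate granule, −0.32 and 0.38 in CA1, −0.39 and 0.36 in CA2 or CA3 and −0.26 and 0.31 in inhibitory neuron-like nuclei, and −0.27 and 0.38 in microglia-like nuclei. The cause was not tested.

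Clusterings agreed on most nuclei: of 18567 kept nuclei, 92.3% had the same class with doublets kept, 86.9% with each library clustered alone, 96.0% at resolution 2 and 87.1% without markers and list genes. In the last of these the microglia-like share was 4.18%, 2.35%, 10.9% and 6.30%, and the dentate granule share 12.9%, 26.4%, 5.56% and 19.5%.

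Over all barcodes, before filtering, Apoe stood at 2471, 18.2, 7443 and 30.2 CPM in WT, EKO, P301S and P301S/EKO.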
